A study of Mus musculus with 10 samples.

How the data were processed

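The measured material was RNA of cells sorted from the midbrain of mice that had received the neurotoxin MPTP and, 3 days after its last injection, a graft of haematopoietic stem and progenitor cells (HSPCs) on one side. Per the labels, cells were dissociated 1 week after the graft and sorted by their fluorescence into red and yellow (RFP+YFP+) hybrid cells, that is graft cells fused with cells of the recipient, and red-only (RFP+) unfused cells. Samples of 2 mice were pooled for each replicate, the RNA was amplified with a whole-transcriptome kit, and 500 ng of cDNA was labelled with Cy3 and hybridised to 1-colour Agilent mouse 8x60K arrays. The 10 arrays form 5 groups of 2 replicates.

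For each array, the authors supplied the spot table of Agilent Feature Extraction 10.7.3.1, in which the deposited processed signal, mean signal and local background are intensities, per the file headers. The processed signal is background-subtracted and detrended within the array and not normalised between arrays. The same tables hold, per the file headers, 0 or 1 marks of each spot, of which the mark for a spot well above background and the marks for non-uniform spots were used. The authors also deposited a matrix of log2 values. On each array that matrix follows the rank order of mean signal minus local background (Spearman's rho across spots 1), and its sorted values are nearly identical between the arrays of a slide, within 0.00182 on the log2 scale. Its median is 7.39 on each of the 6 arrays of the slide with R26Y and GFAP-Cre samples and 6.26 on each of the 4 FoxA2-Cre arrays. The tool behind the matrix is not stated. All samples were matched to their files, with 0 columns of unmatched samples.

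Each array held 62976 spots, of which 59305 were not controls, for 55681 probes. Gene names were taken from the arrays' own annotation and updated through RefSeq accessions: 27428 probes matched an accession, 2788 of them changed name, and 28253 did not match and kept the name in the file. Probe coordinates are those of the array files, on mouse genome build mm9. Probe positions were not remapped, because no genome sequence was at hand.

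The values used were log2 of the processed signal minus the 75th percentile of the same array, taken over spots well above background on all 10 arrays. Spots marked as non-uniform were left out and spots of a probe were averaged. A probe was kept when it was well above background on at least 2 arrays, and each gene was represented by its probe with the highest mean over all arrays, which left 32165 genes or unnamed transcripts tested. Depth is given as the share of spots well above background, and the number of arrays limits the precision. A fold is a lower bound, written as at least, where 1 group was not well above background on any of its arrays. In that case the background level replaces the group's value.

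Comparisons used limma 3.58.1 in R 4.3.3 (linear model with moderated, two-sided tests), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. All hybrids were compared with all unfused cells with the recipient set as a covariate (7 residual degrees of freedom). The single hybrid types were compared with the unfused cells of their own recipient set from 5 group means with a shared spread (5 residual degrees of freedom). The difference between recipient sets in the hybrid effect was tested as an interaction. The 24 marker lists were tested with camera at a preset correlation of 0.01, adjusted over the 96 tests of 24 lists in 4 comparisons, and again with an estimated correlation. The lists covered astrocytes, reactive astrocytes, dopaminergic neurons, neurons, neural progenitors, oligodendrocytes, microglia, monocytes and macrophages, neutrophils, haematopoietic stem and progenitor cells, erythroid cells, lymphoid cells, endothelium and pericytes, Wnt ligands, Wnt receptors and modulators, Wnt targets, cell cycle, inflammatory mediators, the interferon response, neurotrophic factors, pluripotency, cell fusion and migration, immediate early and stress genes, and the p53 response. Mean list levels per array were compared by an exact permutation of the cell labels within each recipient set, and camera was run on the same arrangements; both tests were added after the data were seen.

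The samples, comparisons, lists, tests, alternatives and the rule for named genes were chosen before the data were examined. By that rule, the genes named in a comparison are, among genes with a symbol whose arrays do not overlap between the groups, the 10 largest rises and the 10 largest falls past the threshold. Where fewer than 5 passed in a direction, genes are named from the 5 with the smallest p in that direction and said not to pass. Up to 4 members of a list with the smallest p are named, and Gfap, Th, Foxa2, Wnt1, Ptprc and Kit are always reported. For the interaction, up to 5 genes per direction are named.

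The alternatives were normexp background correction (offset 50), quantile normalisation, the percentile over all probes, the authors' matrix, no filter or a filter at 5 arrays, the mean of a gene's probes, limma-trend with robust variances, array weights, only the arrays compared, no recipient set term, blocks for replicate number, slide row and slide column, leaving out each array in turn, and the estimated correlation. Leaving out probes that share 20 bases with a probe of another gene, and keeping only the slide with R26Y and GFAP-Cre samples, were added after the data were seen. Replicate numbers shared between groups carried no pairing: deviations of replicate 1 from replicate 2 correlated across genes between -0.0711 and 0.0729 for pairs of groups, and genes are not independent replicates.

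The procedure was tested on simulated data with the spread of these arrays, in which 200 genes were given a known change. At a log2 change of 2, 0% of them were recovered in any of the 4 hybrid comparisons. At a log2 change of 5, 90% were recovered for all hybrids, 51.5% for R26Y hybrids, 60% for GFAP-Cre hybrids and 62% for FoxA2-Cre hybrids, with 4 or 5 false calls in each. A list of 15 members shifted by -2 was called in each of these comparisons, and 5 to 7 of 200 random lists fell under 0.05 unadjusted. These rates do not cover arrays that differ in spread, as the real ones do. They also cannot check the preset correlation, since the simulated genes were uncorrelated. The tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.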

Results

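Transcript levels were measured on 10 arrays of sorted graft-derived cells in 5 groups of 2 replicates. R26Y recipients carry a YFP reporter that Cre recombinase switches on, and the HSPCs grafted into them carried Cre and RFP. GFAP-Cre and FoxA2-Cre recipients express Cre in cells with an active Gfap or Foxa2 promoter, Gfap being an astrocyte filament gene and Foxa2 a transcription factor gene of the ventral midbrain, and received HSPCs with the R26Y reporter. The groups were hybrids from R26Y, GFAP-Cre and FoxA2-Cre recipients, unfused cells pooled from R26Y and GFAP-Cre recipients, and unfused cells from FoxA2-Cre recipients. Each comparison asks how red and yellow hybrid cells differ from red-only graft cells, called unfused here. In GFAP-Cre and FoxA2-Cre recipients, YFP marks fusion with a Cre-expressing cell only. Red-only cells from them may therefore include graft cells fused with other recipient cells.

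Spots well above background made up 84.1% and 64.3% on the R26Y hybrid arrays, 81.4% and 82.4% on the GFAP-Cre hybrid arrays, and 82.8% and 86.7% on the pooled unfused arrays. The FoxA2-Cre arrays were dimmer, at 34.6% and 19.8% for hybrids and 49.2% and 34.8% for unfused cells. No spot was saturated. All 6 R26Y and GFAP-Cre arrays were on 1 slide and all 4 FoxA2-Cre arrays on another, so recipient set and slide coincide. On the FoxA2-Cre slide, both hybrid arrays lay in row 1 and both unfused arrays in row 2. On the other slide, pooled unfused replicate 1 and GFAP-Cre hybrid replicate 1 were each the only array of their column. A slide column block therefore takes up these arrays whole. Replicates correlated across genes with Spearman's rho of 0.951 for pooled unfused cells, 0.904 for GFAP-Cre hybrids, 0.718 for FoxA2-Cre unfused cells, 0.678 for R26Y hybrids and 0.670 for FoxA2-Cre hybrids. Genes are not independent replicates in these values.

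**Figure D1:**
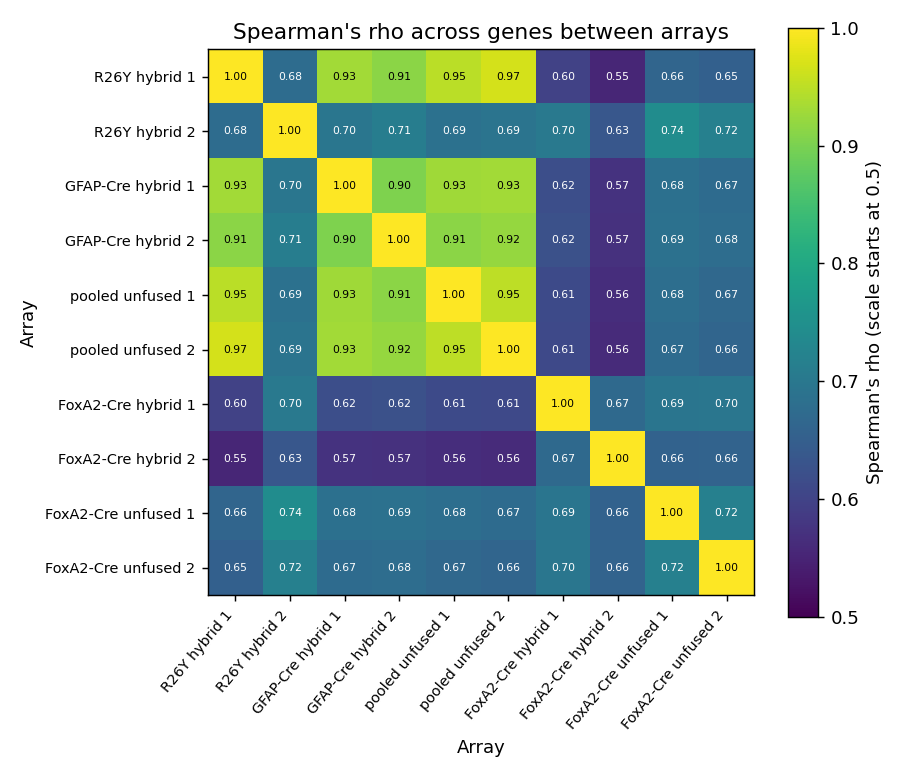
Spearman's rho across genes between each pair of the 10 arrays (colour scale from 0.5 to 1, unitless). R26Y hybrid replicate 2 has a median rho of 0.693 with the other 5 arrays of its slide, and 0.743 and 0.718 with the FoxA2-Cre unfused arrays.

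Mpo and S100a9, which encode proteins of neutrophil granules and cytosol, had the largest gaps between hybrids and unfused cells among the neutrophil genes named. The mean Mpo level was -6.32 ± 0.63 (log2 scaled signal, SD, n = 6) in all hybrids and -0.31 ± 2.64 (SD, n = 4) in unfused cells. The fitted log2 difference for Mpo was -5.71 ± 0.86 (SE), and that for S100a9 was -5.46 ± 1.20 (SE). Both genes were lower in 6 of 6 hybrid arrays than the unfused mean of their recipient set. Neither passed the correction in limma (adjusted p 0.999 for each). As a list, the 15 neutrophil genes were lower in all hybrids than in unfused cells, with a median log2 difference of -0.92 and 11 of 15 members below 0 (camera, adjusted p 0.000253). The call is lost with an estimated correlation (adjusted p 0.543, unadjusted p 0.00566). On the slide with R26Y and GFAP-Cre samples alone the adjusted p was 0.00107. For FoxA2-Cre hybrids against their unfused cells, with the spread shared by all arrays, it was 0.0245. Of the 15 genes, 0 passed over all genes tested and 3 passed as lower when adjusted over the list alone.

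The mean level of the neutrophil list lay between -4.73 and -3.19 on the 6 hybrid arrays and between -2.74 and -2.20 on the 4 unfused arrays, with no overlap. An exact permutation of the labels within recipient sets gave a two-sided p of 0.0222 over 90 arrangements (adjusted p 0.267 over 24 lists). The microglia list, with genes of the resident macrophages of the brain, showed the opposite order. Its mean level lay between -2.73 and -1.79 on hybrid arrays and between -2.89 and -2.83 on unfused arrays, with the same exact permutation p of 0.0222 and adjusted p of 0.267. In camera its median log2 difference was 0.41, with 6 of 16 members below 0, and the list did not pass (adjusted p 0.134). It passed with normexp (adjusted p 0.0492), the authors' matrix (0.00408), array weights (0.0176), only the slide of R26Y and GFAP-Cre samples (0.0452), and without FoxA2-Cre hybrid replicate 2 (0.0358). With an estimated correlation its adjusted p is 0.714. It passed under no other setting, with an adjusted p of 0.869 with slide column, 0.656 without shared probes and 0.482 without the recipient set term. Among its members, the log2 difference was 1.62 ± 0.58 (SE) for Cx3cr1, a chemokine receptor gene of microglia, and 3.96 ± 1.65 (SE) for Trem2, a myeloid surface receptor gene. Both were higher in 6 of 6 hybrid arrays than the unfused mean of their recipient set (adjusted p 0.999 for each).

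**Figure D2:**
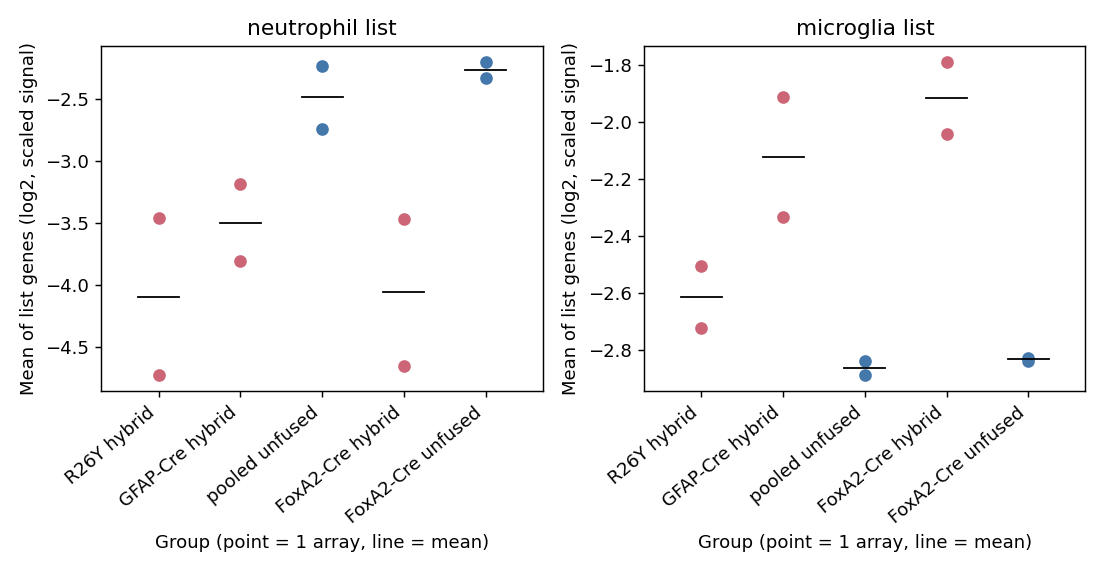
Mean log2 scaled signal of the neutrophil and microglia lists, 1 point per array and a line at each group mean, hybrids in red and unfused cells in blue. Neutrophil means lie between -4.73 and -3.19 on hybrid arrays and between -2.74 and -2.20 on unfused arrays.

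Across all hybrids, limma called 0 of 32165 genes (1006 at an unadjusted p under 0.05), and the median log2 difference of all genes was 0.03. Among the genes with the smallest p were Eps8l1 (2.52 ± 0.43, SE), Figla, Ambra1, Kis2 and Krt90 on the higher side and Mpo, Atp5g3, S100a9 and Def8 on the lower side, and none passed. Gfap lay at -4.69 ± 1.04 (SD, n = 6) in hybrids and -4.06 ± 1.70 (SD, n = 4) in unfused cells, a fitted difference of -0.996 ± 0.463 (SE). The fitted difference was -0.40 ± 0.34 (SE) for Th, the gene of the enzyme that limits dopamine synthesis, and 0.28 ± 0.36 (SE) for the signalling ligand gene Wnt1. For Foxa2, the blood cell marker Ptprc and the stem cell factor receptor gene Kit it was -0.61 ± 0.71, -0.08 ± 0.30 and -0.14 ± 0.36 (SE). The adjusted p of each of these 6 genes was 0.999, and the signs for Foxa2, Ptprc and Kit differed between scalings.

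The other lists did not pass in the comparison of all hybrids with unfused cells. For glial lists the median log2 difference was 0.04 for astrocytes (adjusted p 0.866), -0.02 for reactive astrocytes (0.689) and 0.03 for oligodendrocytes (0.879). Neural lists gave 0.09 for dopaminergic neurons (0.879), 0.12 for neurons (0.925) and 0.09 for neural progenitors (0.908). Blood and vessel lists gave 0.36 for haematopoietic stem and progenitor cells (0.856), 0.42 for erythroid cells (0.667), -0.07 for lymphoid cells (0.989), -0.15 for monocytes and macrophages (0.689) and -0.16 for endothelium and pericytes (0.689). Wnt ligands had a median of 0.05 (0.933), Wnt receptors and modulators -0.01 (0.917) and Wnt targets 0.10 (0.998). Among process lists, medians were -0.51 for cell cycle (0.134), -0.13 for inflammatory mediators (0.908), -0.12 for the interferon response (0.689) and -0.20 for the p53 response (0.879). The cell cycle list passed at 0.0248 with the mean of a gene's probes, and its adjusted p was 0.976 with an estimated correlation. The remaining medians were 0.00 for neurotrophic factors (0.998), 0.05 for pluripotency (0.917), -0.10 for cell fusion and migration (0.917) and -0.21 for immediate early and stress genes (0.689). The direction in camera and the sign of the median differed for the astrocyte, dopaminergic neuron, oligodendrocyte, lymphoid, Wnt receptor, Wnt target, neurotrophic factor and cell fusion lists. Median and mean differed in sign for the neuron, Wnt ligand and pluripotency lists among others.

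In R26Y hybrids, Mpo lay at -6.60 ± 1.06 (SD, n = 2) against -2.29 ± 2.26 (SD, n = 2) in pooled unfused cells, a log2 difference of -4.31 ± 1.05 (SE). The neutrophil list was lower, with a median of -1.31 and 14 of 15 members below 0 (adjusted p 0.0245), and its mean level was lower on 2 of 2 hybrid arrays. The list did not pass without R26Y hybrid replicate 1 (adjusted p 0.651) or pooled unfused replicate 1 (0.0994), nor with slide row (0.174) or slide column (0.0920) as a block or with array weights (0.0792). With an estimated correlation the adjusted p is 0.976. No member passed over all genes tested or adjusted over the list alone (0 in each case). Olfr952, an odorant receptor gene whose probe shares sequence with another gene, was the gene of smallest p on the higher side, at 3.09 ± 0.57 (SE), and Fam170a on the lower side, at -3.39 ± 0.62 (SE); both fell short of the threshold. In limma 0 genes passed (445 at an unadjusted p under 0.05; median of all genes -0.26). The 2 replicates differed in depth, and without replicate 1 of the R26Y hybrids 2316 genes were called, resting on the single dimmer array.

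In GFAP-Cre hybrids, Grn, which encodes the lysosomal protein progranulin, lay at -3.77 ± 0.42 (SD, n = 2) and was below background in pooled unfused cells, at least 12.02-fold higher in hybrids. Its log2 difference of 3.61 ± 0.53 (SE) did not pass the correction (limma p 0.000157, adjusted p 1.00). Mpo differed by -3.86 ± 1.05 (SE). The neutrophil list was lower, with a median of -0.81 and 13 of 15 members below 0 (adjusted p 0.00181), lower on 2 of 2 hybrid arrays. It did not pass without GFAP-Cre hybrid replicate 2 (adjusted p 0.0636) or pooled unfused replicate 1 (0.0586), nor with slide column (0.542, unadjusted p 0.0937) or slide row (0.0625) as a block. The column block takes up GFAP-Cre hybrid replicate 1 and pooled unfused replicate 1 whole, so this loss does not show a column effect. With an estimated correlation the adjusted p of the neutrophil list is 0.714, and 0 members passed over all genes or adjusted over the list alone. The microglia list had a median of 0.55 with 2 of 16 members below 0 and did not pass (adjusted p 0.0542, and 0.714 with an estimated correlation). It passed under each of the 4 other scalings (adjusted p 0.000210 to 0.0333), and without R26Y hybrid replicate 1 (0.0211) or 2 (0.0158). Among its members, the complement gene C1qc differed by 2.40 ± 1.25 (SE). The endothelial and pericyte list had a median of -0.25 and did not pass (adjusted p 0.0986), but passed as lower without R26Y hybrid replicate 2 (0.0446). In limma 0 genes passed (520 at an unadjusted p under 0.05; median of all genes 0.03). R26Y and GFAP-Cre hybrids were compared with the same 2 unfused arrays, so these differences are not independent.

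FoxA2-Cre hybrids were the hybrid type with called genes. Rps27a, a ribosomal protein gene, fell from 4.15 ± 0.14 (SD, n = 2) in unfused cells to -4.88 ± 0.40 (SD, n = 2) in hybrids, a log2 difference of -9.03 ± 0.48 (SE, adjusted p 0.00209). Pfn1, which encodes an actin-binding protein, was at least 147-fold lower, with a log2 difference of -8.21 ± 0.63 (SE, adjusted p 0.00340). Mpo fell by 7.89 on the log2 scale (adjusted p 0.0258), and S100a9 was at least 201-fold lower (log2 difference -8.60 ± 1.33, SE; adjusted p 0.0470). Vmn1r148, a vomeronasal receptor gene whose probe shares 20 bases with a probe of another gene, rose by 10.06 ± 0.85 (SE, adjusted p 0.00490), at least 983-fold. Commd2, whose protein belongs to a family that regulates protein sorting, rose by 10.03 ± 1.02 (SE, adjusted p 0.00902), at least 288-fold. Fabp5, a fatty acid binding protein gene, also with a shared probe, rose by 4.72 ± 0.68 (SE, adjusted p 0.0361). Each of these genes lay on the stated side on 2 of 2 hybrid arrays without overlap with unfused cells. The naming rule requires this of genes past the threshold, so it adds no support to the calls.

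In total, 171 genes passed in limma, 17 higher and 154 lower in FoxA2-Cre hybrids (2780 at an unadjusted p under 0.05). With the authors' matrix the split was 38 higher and 129 lower. It changed when 1 FoxA2-Cre array was left out, to 135 higher and 196 lower without hybrid replicate 1, 245 and 191 without hybrid replicate 2, 19 and 334 without unfused replicate 1, and 15 and 542 without unfused replicate 2. Without any 1 pooled unfused or GFAP-Cre hybrid array 61 genes passed, and without either R26Y hybrid array 268. Of the 17 higher genes, 11 (64.7%) had a probe that shares 20 bases with a probe of another gene, against 39.6% of the 154 lower genes and 12.9% of all genes tested. With such probes left out, 3 genes were called higher and 57 lower. The median log2 difference of all genes was 0.36, and between 0.03 and 0.71 under the other scalings. Relative to the median of 0.36, Rps27a changed by -9.39, Mpo by -8.25, Vmn1r148 by 9.70 and Commd2 by 9.67. The other named rises were Vmn1r132, with a shared probe, and Snw1, and the other named falls were Antxr2 (at least 406-fold), Cpsf6, Dennd5a, Mettl21c, Orly and Igh-VJ558. On build mm9, the probe of Rps27a lies on chromosome 11 at 29445914 to 29445973, that of Pfn1 on chromosome 11 at 70465688 to 70466312, that of Vmn1r148 on chromosome 7 at 21454870 to 21454929 and that of Commd2 on chromosome 3 at 57450284 to 57450343. The probe of Mpo lies on chromosome 11 at 87617840 to 87617899 and that of S100a9 on chromosome 3 at 90496573 to 90496632. With the spread taken from the 4 FoxA2-Cre arrays alone, 0 genes passed (1407 at an unadjusted p under 0.05). With slide row or slide column in the model 0 passed as well (2336 and 1338 at an unadjusted p under 0.05).

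The neutrophil list was lower in FoxA2-Cre hybrids, with a median log2 difference of -0.55 and 10 of 15 members below 0 (adjusted p 0.0245), and its mean level was lower on 2 of 2 hybrid arrays. The list did not pass without hybrid replicate 1 (adjusted p 0.358), unfused replicate 1 (0.0722) or unfused replicate 2 (0.135), nor with slide row as a block (0.0945), the filter at 5 arrays (0.0819) or array weights (0.0612). With an estimated correlation the adjusted p is 0.976. Mpo and S100a9 were the 2 members that passed over all genes, and 3 passed adjusted over the list alone. Camp, an antimicrobial peptide gene of neutrophils, differed by -6.17 ± 1.02 (SE, adjusted p 0.0586, lower on 2 of 2 hybrid arrays).

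The hybrid effect in FoxA2-Cre recipients was then compared with that in R26Y and GFAP-Cre recipients. Rps27a differed between the recipient sets by -8.82 ± 0.64 (log2, SE, adjusted p 0.0191), Orly, a gene assigned to unplaced Y sequence, by -7.89 ± 0.66 (adjusted p 0.0191), and Pfn1 by -7.99 ± 0.83 (adjusted p 0.0272). The ribosomal protein gene Rpl31 differed by -5.99 ± 0.64 (adjusted p 0.0278). Vmn1r148 differed by 10.75 ± 1.13 (adjusted p 0.0272) and Commd2 by 11.39 ± 1.35 (adjusted p 0.0432). In all, 31 genes passed, 4 higher and 27 lower (1806 at an unadjusted p under 0.05; median of all genes 0.40). With slide row, slide column or replicate number as a block 0 passed in limma (2811, 549 and 1667 at an unadjusted p under 0.05), and without shared probes 5 passed. The others that passed carry no symbol under the naming rule. Among genes with a symbol, Vmn1r132, Hipk3 and Snw1 followed by p on the higher side and Oaz1 on the lower side, and none of these passed. Leaving out either pooled unfused array or either GFAP-Cre hybrid array left 0 genes called. Without either R26Y hybrid array 81 passed. The split was 53 higher and 70 lower without FoxA2-Cre hybrid replicate 1, 101 and 51 without replicate 2, 4 and 91 without FoxA2-Cre unfused replicate 1, and 8 and 148 without its replicate 2. For Mpo the effect differed between recipient sets by -3.80 (adjusted p 0.835) and for S100a9 by -5.48 (adjusted p 0.773), so neither passed.

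GFAP-Cre and R26Y hybrids were compared with each other within 1 slide. Bcl2a1d, an anti-apoptotic gene of blood cells, lay at -2.93 ± 0.52 (SD, n = 2) in GFAP-Cre hybrids and at -7.88 ± 1.10 (SD, n = 2) in R26Y hybrids, where it was below background, at least 15.1-fold higher. Hgsnat, a lysosomal enzyme gene, differed by -6.45 ± 1.51 (SE). Both lay on the stated side on 2 of 2 arrays and neither passed (adjusted p 1.00 for each). In limma 0 genes passed (882 at an unadjusted p under 0.05; median of all genes 0.29). Without R26Y hybrid replicate 1, 2183 genes were called against the single remaining R26Y hybrid array.

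Unfused cells of FoxA2-Cre recipients and pooled unfused cells differed in 54 genes in limma, 10 higher and 44 lower in FoxA2-Cre (5614 at an unadjusted p under 0.05). Recipient set and slide cannot be told apart here. The median log2 difference of all genes was -0.46 and went from -1.24 with the authors' matrix to 0.73 with normexp. The split turned with 2 scalings, to 34 higher and 14 lower with normexp and 9 and 7 with the percentile over all probes. It kept its direction with quantile normalisation (7 and 21) and the authors' matrix (61 and 16359). Among left-out arrays, it turned without FoxA2-Cre unfused replicate 1 (48 and 31) or replicate 2 (140 and 81). No gene passed (0) without any 1 pooled unfused or GFAP-Cre hybrid array, and 2671 passed without either R26Y hybrid array. With slide row, slide column or replicate number as a block 0 passed in limma (5633, 1082 and 5141 at an unadjusted p under 0.05).

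Chemoreceptor genes, the odorant, vomeronasal and taste receptors of sensory neurons, were measured by 1530 probes. Of these, 90.6% were well above background on R26Y hybrid replicate 1 and 59.2% on replicate 2. The values were 88.2% and 89.2% on GFAP-Cre hybrid arrays and 89.3% and 92.2% on pooled unfused arrays. On FoxA2-Cre arrays they were 25.8% and 11.2% for hybrids and 40.8% and 27.0% for unfused cells. Of 308 hairpin negative control spots, at most 0.649% were well above background on any array. As a comparison measured in the same way, 106 control probes for spike-in RNAs of non-mouse sequence were well above background in 57.5% and 61.3% of cases on R26Y hybrid arrays, 67.9% and 66.0% on GFAP-Cre hybrid arrays, 51.9% and 66.0% on pooled unfused arrays, 16.0% and 9.43% on FoxA2-Cre hybrid arrays, and 35.8% and 19.8% on FoxA2-Cre unfused arrays. Whether spike-in RNA was added is not stated, and the sequences of these control probes are not in the files, so they were not matched for GC content. A probe well above background is not taken as expression of its gene here.

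**Figure D3:**
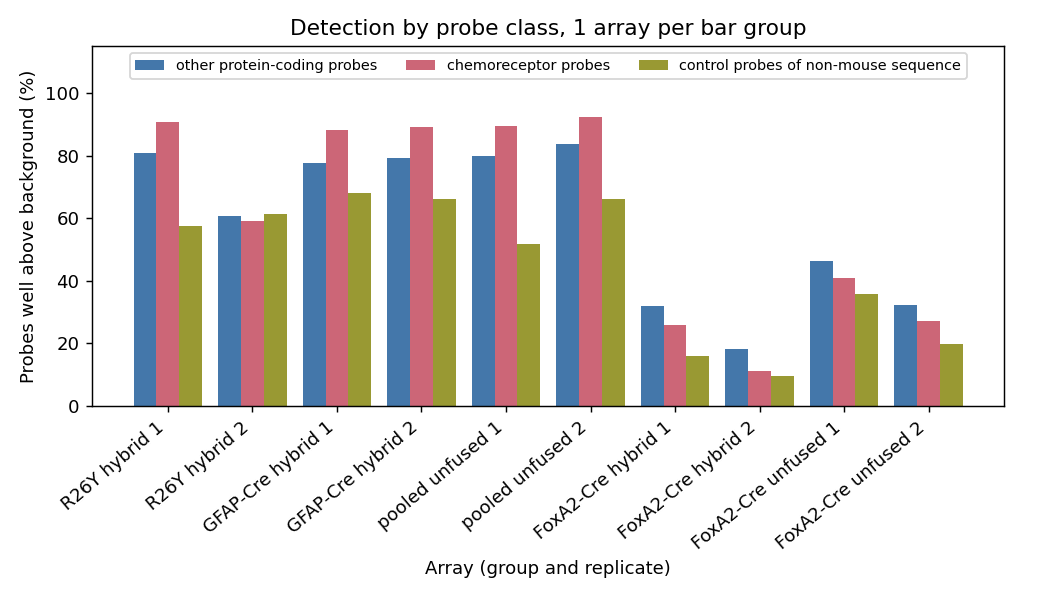
Probes well above background (%, bars from 0) on each of the 10 arrays, for other protein-coding genes, chemoreceptor genes and control probes of non-mouse sequence. Chemoreceptor probes reach 92.2% on a pooled unfused array and 11.2% on a FoxA2-Cre hybrid array.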

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

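The tests for genomic DNA, unspecific hybridisation, shared probe sequence, low signal and a mislabelled FoxA2-Cre unfused array were chosen only after the results they concern were seen, and the verdict rules for unspecific hybridisation, shared sequence, low signal and slide row were made stricter after their values were known.

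Among 24 groups of arrays examined for a single distant array, 2 had one, and chance gives about 1 in 20. The mean of the microglia list on pooled unfused replicate 2 was -2.89, and the other 3 unfused arrays lay at -2.84, -2.84 and -2.83. This gap is small beside the range of the hybrid arrays, -2.73 to -1.79, and was flagged because those 3 lie so close together. Th on FoxA2-Cre hybrid replicate 2 was -2.01, below the other 5 hybrid arrays.

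The hybrid effect differed between recipient sets for 31 genes in the interaction test, for 0 with slide row, slide column or replicate number as a block, and for 5 without shared probes. The named genes were Vmn1r148 (10.75), Commd2 (11.39), Rps27a (-8.82), Orly (-7.89), Pfn1 (-7.99) and Rpl31 (-5.99), as log2 differences between the effect in FoxA2-Cre and that in R26Y and GFAP-Cre recipients. Control probes of non-mouse sequence, which no comparison uses, were well above background on up to 67.9% (GFAP-Cre hybrid replicate 1).

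Chemoreceptor probes were well above background in 88.2% to 92.2% of cases on 5 arrays of the R26Y and GFAP-Cre slide and in 59.2% on R26Y hybrid replicate 2. Unspecific hybridisation stays open: the chemoreceptor minus control difference on each of the 5 arrays exceeded that of R26Y hybrid replicate 2 by at least 1.74 (log2), but that array is the only reference, and the control probes, for spike-in RNAs whose use is not stated, were not matched for GC content. Genomic DNA amplified with the RNA may contribute, and cannot be told apart from other sources. Within 720 genes, probes across exon junctions minus contiguous probes should then lie lower on the 5 arrays. On GFAP-Cre hybrid replicate 1 the median lay 0.138 higher than on R26Y hybrid replicate 2 (95% bootstrap interval -0.0952 to 0.296). On the other 4 arrays it differed by -0.40 to -0.11. The interval lay below 0 for R26Y hybrid replicate 1 (-0.430 to -0.0354) and pooled unfused replicate 1 (-0.625 to -0.211). It spanned 0 for pooled unfused replicate 2 and GFAP-Cre hybrid replicate 2. FoxA2-Cre unfused replicate 1, with 40.8% of chemoreceptor probes well above background, also lay lower (-0.249, interval -0.478 to -0.0628). A lower median was thus not confined to the 5 arrays. No biological explanation was tested.

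Among the 154 genes lower in FoxA2-Cre hybrids, 61 (39.6%) had a probe that shares 20 bases with another gene, 3.07 times the share of all genes tested (Fisher's exact two-sided p 7.41e-17), and among the 17 higher genes 11 (64.7%) had one, 5.02 times that share. Among genes of like level the expected share is 27.0%, so bright signal could account for much of it, and 93 of the 154 genes have no such probe. A row effect common to both slides needs these genes to lie lower in row 1 on the other slide too. There, row 1 minus row 2 had a median of 0.122 in R26Y hybrids (95% bootstrap interval over genes -0.342 to 0.337, which spans 0). The row 1 array of R26Y hybrids is replicate 2, which lay apart from its slide, so row and that difference coincide there. In GFAP-Cre hybrids it was 0.113 (0.0313 to 0.186), and the medians over all genes were -0.526 and 0.199. These values argue against a common row effect of the size seen in FoxA2-Cre hybrids (median log2 size 6.46). Relative to all genes the 2 hybrid types differ in direction, and each difference rests on 1 array per row. A smaller common row effect therefore stays open. A row effect particular to the FoxA2-Cre slide cannot be told apart from cell type, since rows and groups coincide there: with row as a block the median log2 size stayed at 6.42 against 6.46, while its SE went from 0.749 to 1.04 and the smallest adjusted p was 0.0814. A difference between hybrid and unfused cells of FoxA2-Cre recipients stays open and untested.

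R26Y hybrid replicate 2 correlated with the other 5 arrays of its slide at a median rho of 0.693, while those 5 had 0.913 to 0.941 among themselves. On the 171 called genes, with 0 at the FoxA2-Cre unfused mean and 1 at the hybrid mean, a mislabelled FoxA2-Cre hybrid array should lie near 1. The median position of R26Y hybrid replicate 2 was 0.281, and the other arrays of its slide lay at 0.279 to 0.317. These genes were called on the arrays that set 0 and 1, where cell type and slide row coincide. The position therefore argues against such a mislabelling only if the calls reflect cell type. For a mislabelled FoxA2-Cre unfused array speak this array's rho of 0.743 and 0.718 with the 2 FoxA2-Cre unfused arrays, against 0.678 to 0.711 with its own slide. A sample number that its file shares with that of FoxA2-Cre unfused replicate 2 also speaks for it. The neutrophil list goes the other way. Its mean of -4.73 on this array lay below the nearer FoxA2-Cre unfused array (difference -2.40, 95% bootstrap interval over genes -4.27 to -0.736). It was 1.99 below the lowest of the 4 unfused arrays, whose range was 0.541. That list was also lower in all hybrids without this array (camera, adjusted p 0.000389). But other lists were low on this array too: cell cycle lay at -5.48 and the p53 response at -4.80. The lowest unfused arrays had -4.60 and -3.61. Whether this array is a mislabelled FoxA2-Cre unfused array therefore stays open. Lower signal may contribute, as 64.3% of its spots were well above background, but its rho exceeded the highest of the dimmer FoxA2-Cre arrays by only 0.0120, and those are on another slide, so signal and slide cannot be told apart. No biological explanation was tested.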

How the results depend on the processing

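Leaving out probes that share 20 bases with another gene, and keeping only the slide with R26Y and GFAP-Cre samples, were tests chosen only after the results were seen; the others were planned. The count of 0 genes for all hybrids and for GFAP-Cre hybrids held under every alternative run, and those for R26Y hybrids and for GFAP-Cre against R26Y hybrids in all but 1. The 91 differences of named genes gave 2186 values over these settings, of which 1957 kept their sign and side of the threshold, 14 changed sign, 182 lost a call and 33 gained one.

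For FoxA2-Cre hybrids against unfused cells, the 171 genes became 111 with normexp (89 of them among the 171), 102 with array weights (all among the 171) and 60 without shared probes (59 among the 171). Using only the 4 arrays compared gave 0. Degrees of freedom and spread both changed here, so neither can be singled out. Slide row or column as a block gave 0, the replicate block 106. For the interaction, the 31 genes became 9 with quantile normalisation, 55 with the authors' matrix, 56 with limma-trend, 5 without shared probes, and 0 with the replicate block, slide row or slide column. For unfused FoxA2-Cre against pooled unfused cells, the 54 genes became 28 with quantile normalisation, 16 with the percentile over all probes, 16420 with the authors' matrix, which was normalised within each slide, 750 with array weights, 89 with limma-trend, 1699 with only the arrays compared, and 0 with the replicate block, slide row or slide column. Except where a construction is named, the cause was not tested.

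The 4 list calls became 2 with slide column, 1 with slide row and 0 with the estimated correlation. The direction of the neutrophil list stayed lower in each of the 4 comparisons under every setting run, but its calls did not all hold. In R26Y hybrids the call was also lost with array weights (adjusted p 0.0792), slide row (0.174) and slide column (0.0920), in GFAP-Cre hybrids with slide row (0.0625) and slide column (0.542), and in FoxA2-Cre hybrids with array weights (0.0612), the filter at 5 arrays (0.0819) and slide row (0.0945). With 1 array left out its adjusted p reached 0.00492 in all hybrids, 0.651 in R26Y hybrids, 0.0636 in GFAP-Cre hybrids and 0.358 in FoxA2-Cre hybrids. Besides microglia, 2 lists gained a call under 1 setting each: cell cycle in all hybrids with the mean of a gene's probes (0.0248), and endothelium and pericytes in GFAP-Cre hybrids without R26Y hybrid replicate 2 (0.0446). The microglia list in GFAP-Cre hybrids passed with normexp (adjusted p 0.000210), quantile normalisation (0.00347), the percentile over all probes (0.0333) and the authors' matrix (0.000921), and also with the filter at 5 arrays (0.0197), limma-trend (0.0420), array weights (0.0240), only the arrays compared (0.00501) and the single slide (0.0452); over all settings without a left-out array, its adjusted p reached 0.961 with slide column.

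Leaving out 1 array at a time, a lone replicate was assumed to vary like the other groups. R26Y hybrids gave 0 to 2316 genes and GFAP-Cre against R26Y hybrids 0 to 2183, each highest without R26Y hybrid replicate 1. FoxA2-Cre hybrids gave 61, without any 1 pooled unfused or GFAP-Cre hybrid array, to 557, without FoxA2-Cre unfused replicate 2. The interaction gave 0 to 156 at the same arrays. The unfused comparison gave 0 to 2671, highest without either R26Y hybrid array. List calls numbered 2, without pooled unfused replicate 1, to 6, without R26Y hybrid replicate 2.

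Signs changed for genes that were not called with all arrays. In all hybrids, Foxa2 was 0.17 with normexp and 0.00935 with the authors' matrix, and -1.05 to 0.0452 with 1 array left out. Ptprc was 0.17 with normexp, 0.0879 with quantile normalisation, 0.0273 with the percentile over all probes, 0.0819 with the authors' matrix and 0.00860 with slide column, and -0.16 to 0.0172 with 1 array left out. Kit was 0.23 with normexp and -0.39 to 0.0945 with 1 array left out. Olfml3 in GFAP-Cre hybrids was -0.0229 with the mean of a gene's probes, and Ctsg there 0.11 with slide column. Ngp in FoxA2-Cre hybrids was -7.29 without unfused replicate 1, where it was called (adjusted p 0.0143), and 0.71 without unfused replicate 2. The cause was not tested.

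Signal over background limits the FoxA2-Cre comparisons, whose arrays had 19.8% to 49.2% of spots well above background, and 2 arrays per group limit all of them.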

Other observations

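The tests with only the slide of R26Y and GFAP-Cre samples, with splits within recipient sets and of mean list levels were chosen only after the results were seen. Of 100 splits of the 10 arrays into 6 and 4, the real one included, 1 gave a p for the neutrophil list as small as the real 2.64e-06, namely the real split, and the smallest p of the others was 0.00195. These splits mix the recipient sets. Of the 90 arrangements within recipient sets, 1 gave a p as small for any of the 24 lists, again the real one, a share of 0.0111 and the smallest they can give; the smallest p of the others was 0.000497. By this share, the p of camera argues against chance for the neutrophil list but does not exclude it. Its mean level had an exact permutation p of 0.0222 (adjusted p 0.267 over 24 lists), which the microglia list shares. With 90 arrangements no single list could pass that adjustment, so the adjusted p decides nothing. The neutrophil call is lost with an estimated correlation. For the number of genes changed in all hybrids the count of splits decides nothing, because with a real count of 0 every split gives as many (100 of 100). At an unadjusted p under 0.05, 65 of the other splits gave at least the real 1006 genes, and the highest gave 5813. The highest adjusted count of the other splits was 861 genes, and 3 splits gave any. The split with 861 sets R26Y hybrid replicate 2, both FoxA2-Cre hybrid arrays and FoxA2-Cre unfused replicate 2 against the rest. These are the dimmest arrays of their slides, with 64.3% of spots well above background on one slide and 34.6%, 19.8% and 34.8% on the other. The next highest split, with 520 genes, has FoxA2-Cre unfused replicate 1 in place of replicate 2. At 49.2% that array is the brightest of its slide. Whether signal accounts for these counts was not tested. With only the slide of R26Y and GFAP-Cre samples the count was 0 as well, and the neutrophil list had an adjusted p of 0.00107.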
